A study of Mus musculus with 18 samples.

How the data were processed

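RNA was sequenced from 18 libraries of differentiated 3T3-L1 adipocytes at passage 15, in 6 groups of 3 that were assigned from the sample titles. Per the labels' protocols, ribosomal RNA was removed from 70 ng of total RNA with a bead kit and libraries were made with a TruSeq RNA v2 kit, which does not mark the strand. Per the submitters' processing notes, the authors used bcl2fastq 2.17.1.14, TopHat2 2.0.14, Picard 2.2.4, SAMtools 0.1.19, featureCounts 1.4.6 and edgeR, with genome build mm9. The settings of these tools are not given in the sources used here. The deposited values are raw read counts per gene model, in whole numbers, with no normalization. Per the file headers, the table also gives each gene model's chromosome, exon starts and ends, strand and exon length. Of the 27473 gene models, 1497 list exons on both strands and can hold reads of overlapping genes, which cannot be told apart without strand. Reads shared between near-identical gene copies could be lost or split in such counts.

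The gene models carry UCSC known-gene identifiers. The reference annotation used here is of build GRCm38, not mm9, and 0 of the identifiers occurred in the gene name table or in the RefSeq gene table. No gene name was therefore given to any gene model, and positions are those of the deposited table. The preset panel of 18 genes, the 18 gene lists and cell type markers chosen before the data were examined need gene symbols, and no result of them is given. Names inferred by matching exon and intron lengths to the reference annotation had been tried, and tests of the gene lists, marker lists included, had been run on those names and seen, as had the gene model matched to Irf3. They were withdrawn because names are taken here by identifier only, and nothing from them is used. The naming rule, fixed at the same time, takes, per comparison and direction, the 7 called genes with the largest fitted log2 fold change among those with a mean of at least 5 CPM in the higher group and no overlap between the CPM values of the groups. Its first 2 per direction are given, and its exclusions by symbol could not be applied.

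Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, after filterByExpr by group and TMM scaling, with Benjamini-Hochberg adjustment over the gene models tested and a threshold of 0.05. The overexpression arm was fitted from its 6 libraries. The 4 groups of the knockdown and LPS arm were fitted together from 12 libraries, and 5 contrasts were taken, the interaction included. The biological coefficient of variation was 0.171 in the first fit and 0.0910 in the second. Standard errors were derived as the size of the log2 fold change divided by the square root of the F statistic. CPM values are scaled by the TMM factors, and log2 CPM values used a prior count of 2. Intervals and floors cover counting error only.

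Total counts ran from 22143302 to 34368259 per library. All 18 pairs of replicates differed beyond sampling noise, with a chi-square per degree of freedom from 3.38 to 349.9 over gene models with at least 20 counts in a pair, so no library was taken as deposited more than once. The edgeR step was tested on simulated counts with 200 gene models changed by known folds. For overexpression, over 13931 gene models, it recovered 8.96% of those changed 1.5-fold, 61.2% of those changed 2-fold and 95.5% of those changed 4-fold, and 12 of 122 calls (9.84%) were of unchanged ones. For knockdown, over 14970 gene models, it recovered 62.7%, 88.1% and 95.5%, and 20 of 184 calls (10.9%) were of unchanged ones. For the interaction, over 14970 gene models, it recovered 37.3%, 76.1% and 93.9%, and 10 of 148 calls (6.76%) were of unchanged ones. The share of unchanged ones among the calls was 4.85% for knockdown under LPS, 8.19% for LPS in control and 5.49% for LPS in knockdown, each over 14970 gene models.

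Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE factors, library totals only, no low-count filter, at least 1 CPM in 3 libraries, a 2-fold minimum, the replicate number as a block, each library left out in turn, no chromosome M gene models, only the 6 libraries compared, and all 18 libraries in one fit. Ribosomal RNA genes outside chromosome M could not be left out without names. Overlaps were tested only between comparisons that share no library, by Fisher's exact test.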

Results

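Gene expression was measured by RNA sequencing in 3T3-L1 cells, a mouse fibroblast line that can be differentiated into adipocytes and that carried vectors labelled as raising or lowering expression of the transcription factor IRF3. Mature adipocytes were transduced with lentivirus for 6 days. The 18 libraries form 6 groups of 3. One arm holds cells labelled as overexpressing Irf3 (Irf3_2D), where the labels do not say what 2D stands for or whether the protein was an altered form, and cells given a green fluorescent protein vector (EGFP). The other arm holds cells given a short hairpin RNA against Irf3 (shIrf3) or against luciferase (shLuc), each without and with lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4. LPS was given for a further 6 days, a duration the labels state for the knockdown cells only. Whether cells without LPS were kept for these 6 days is not given here, so LPS and time in culture cannot be told apart. Total counts per library ran from 22143302 to 34368259 over 27473 gene models. No label says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

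The table identifies gene models by UCSC known-gene identifiers and holds no gene symbols, and 0 of the 27473 identifiers occurred in either gene name table used here. Gene models are therefore reported by identifier and position on mouse build mm9, with up to 2 that rose and 2 that fell per comparison. For the same reason the count of the targeted gene, Irf3, in each library is not reported here, and no check of the labels by it is given.

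Libraries of one group differed in depth and in the share of mitochondrial counts. Totals ran from 22143302 to 31434168 in Irf3_2D and from 25172651 to 34368259 in shLuc. Gene models on chromosome M, the mitochondrial genome, held 14.2% of the counts in shLuc replicate 1 and 2.88% in shLuc replicate 2, against 5.19% in shLuc replicate 3. In the shIrf3 libraries the share was 6.78% ± 0.345 (SD, n = 3), in shLuc with LPS 4.37% ± 0.158 and in shIrf3 with LPS 6.10% ± 0.284. It was 2.44% ± 0.249 in Irf3_2D and 2.82% ± 0.293 in EGFP. On the second principal component of the overexpression arm, which held 33.0% of the variance, Irf3_2D replicate 2 lay at -46.7 and the other 5 libraries between -6.71 and 16.0.

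**Figure D1:**
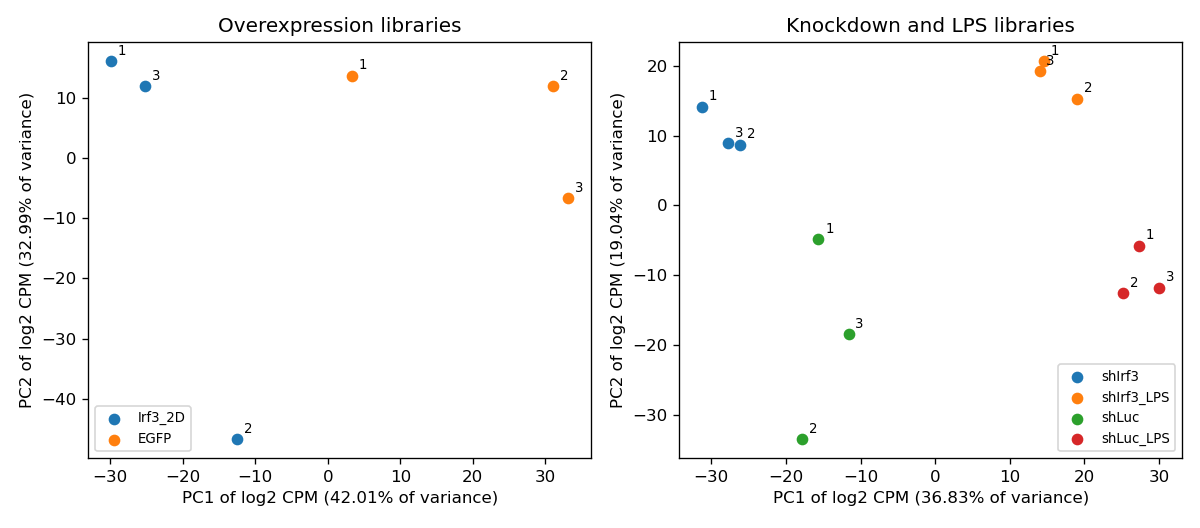
Principal components of log2 CPM, with library sizes scaled by TMM factors, for the 6 libraries of the overexpression arm (left) and the 12 libraries of the knockdown and LPS arm (right). Each point is 1 library, coloured by group and numbered by replicate, and axis labels give the percent of variance; Irf3_2D replicate 2 lies at -46.7 on the second component of the left panel.

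The libraries labelled as overexpressing Irf3 were compared with those of the EGFP vector. Of 13931 gene models tested, 113 were higher and 89 lower. The median log2 fold change was 1.76 among the gene models that rose and -1.24 among those that fell. The gene model uc007nfi.2 on chromosome 12 (27127608 to 27141317, 7 exons) rose from 3.60 ± 4.2 to 85.1 ± 26.5 CPM (SD, n = 3), a log2 fold change of 4.57 with a standard error of 0.75 and an edgeR adjusted p of 0.0331. The gene model uc007nfj.1, also on chromosome 12 (27154080 to 27164702, 5 exons), rose from 2.73 ± 2.77 to 37.1 ± 2.70 CPM (edgeR adjusted p = 0.0196). The 12-exon gene model uc009saj.1 on chromosome 9 (119057161 to 119066211) fell from 8.73 ± 1.32 to 1.23 ± 0.123 CPM, a log2 fold change of -2.82 ± 0.21 (SE, edgeR adjusted p = 0.00173). The gene model uc008wjg.1 on chromosome 5 (7960472 to 7982213, 5 exons) fell from 95.4 ± 37.7 to 18.9 ± 4.34 CPM (edgeR adjusted p = 0.0122). Of the 7 chromosome M gene models tested, 0 were called, with log2 fold changes from -0.36 to 0.39, or from -0.44 to -0.02 without Irf3_2D replicate 2. Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05.

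DESeq2 called 236 gene models higher and 245 lower, edgeR called 464 and 478 with all 18 libraries in one fit, and the edgeR counts moved with single libraries. Without Irf3_2D replicate 2 there were 473 gene models higher and 548 lower, whereas there were 4 and 9 without Irf3_2D replicate 1, 41 and 14 without Irf3_2D replicate 3, 1 and 6 without EGFP replicate 2, 0 and 5 without EGFP replicate 3, and 170 and 105 without EGFP replicate 1. The calls of both gene models named as risen ended without any one Irf3_2D library, without EGFP replicate 2 and without EGFP replicate 3, with log2 fold changes from 4.13 to 4.80 for uc007nfi.2 and from 3.35 to 3.81 for uc007nfj.1. Both calls also ended with no low-count filter, at 4.57 and 3.77, and without EGFP replicate 1 both held, at 6.17 and 5.05. The call of uc008wjg.1 ended without Irf3_2D replicate 1, Irf3_2D replicate 2 or EGFP replicate 3, at log2 fold changes of -2.31, -2.54 and -2.47.

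Knockdown of Irf3 was first compared with shLuc without LPS, where 696 of 14970 gene models were higher and 585 lower, with a median log2 fold change of 0.40 among those that rose and -0.48 among those that fell. At least 2-fold changes were found for 58 higher and 79 lower gene models. The gene model uc007kmt.2 on chromosome 11 (81928687 to 81930301, 3 exons) rose from 1.13 ± 0.478 to 5.31 ± 0.949 CPM (SD, n = 3), a log2 fold change of 2.21 ± 0.23 (SE, edgeR adjusted p = 6.98e-05). The gene model uc008nuj.1 on chromosome 2 (164179806 to 164185150, 5 exons) rose from 3.88 ± 1.88 to 13.6 ± 1.55 CPM (edgeR adjusted p = 0.00299). The gene model uc009kic.1 on chromosome 7 (147949731 to 147960876, 9 exons) fell from 514.5 ± 44.8 to 93.6 ± 24.1 CPM, a log2 fold change of -2.46 ± 0.19 (SE, edgeR adjusted p = 6.49e-05). The gene model uc008hpn.1 on chromosome 19 (44277778 to 44318506, 7 exons) fell from 25.9 ± 1.37 to 5.16 ± 1.55 CPM (edgeR adjusted p = 1.12e-06). All 4 of these calls held in every alternative run for them. The count is not set against that of overexpression, which came from another fit with another detection limit. With all 18 libraries in one fit knockdown had 202 higher and 184 lower and overexpression 464 and 478. These are not to be set against each other either. That fit shares its spread between arms with biological coefficients of variation of 0.171 (overexpression) and 0.0910. The shared spread can be too small for overexpression and too large for knockdown. Of the calls, 54.3% were higher, and 67.1% were with library totals as the only scaling. Fitted from the 6 libraries compared alone, 235 gene models were higher and 201 lower. Pairs of shLuc replicates differed with a chi-square per degree of freedom of 55.9, 199 and 349.9. In the other groups of this arm it ran from 3.38 to 15.6. The shared fit assumes the same spread in all groups. Its p-values can thus be too small for comparisons with shLuc and too large for those without it. Without shIrf3 replicates 1, 2 and 3 in turn there were 284, 366 and 370 higher and 226, 299 and 323 lower, without shLuc replicate 1 there were 1623 and 1121, without shLuc replicate 2 there were 1175 and 888, and without shLuc replicate 3 there were 376 higher and 447 lower, or 45.7% higher.

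Under LPS, knockdown again changed gene models in both directions. Against shLuc with LPS, 733 of 14970 gene models were higher and 495 lower in shIrf3 with LPS, and 98 and 53 of them by at least 2-fold. The gene model uc009ocg.2 on chromosome 9 (7272514 to 7283333, 10 exons) rose from 40.6 ± 2.72 to 151.2 ± 11.0 CPM (SD, n = 3), a log2 fold change of 1.90 ± 0.11 (SE, edgeR adjusted p = 2.61e-07). The gene model uc007kmt.2, which also rose without LPS, went from 6.72 ± 1.06 to 24.6 ± 2.37 CPM (edgeR adjusted p = 1.33e-05). The gene model uc007iza.1 on chromosome 11 (54971970 to 54998579, 10 exons) fell from 5.18 ± 0.398 to 0.687 ± 0.127 CPM, a log2 fold change of -2.92 ± 0.23 (SE, edgeR adjusted p = 2.35e-06). The gene model uc009kic.1 fell from 783.4 ± 37.3 to 163.0 ± 31.5 CPM (edgeR adjusted p = 6.16e-05). With all 18 libraries in one fit 205 were higher and 173 lower. Fitted from the 6 libraries compared alone, 1495 gene models were higher and 1353 lower. Without shIrf3_LPS replicate 1 there were 336 higher and 202 lower, without shIrf3_LPS replicate 3 there were 362 and 198, without shLuc_LPS replicate 2 there were 386 and 226, without shLuc_LPS replicate 3 there were 327 and 209, and without shLuc replicates 1 and 2 in turn, which enter only the shared spread and scaling, there were 1185 and 1329 higher and 865 and 910 lower.

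The 2 knockdown comparisons share no library, and 644 gene models were called in both, all 644 in the same direction. A further 637 were called for knockdown only and 584 for knockdown under LPS only, which is no test of a difference between them. Of the gene models higher with knockdown, 386 were also higher with knockdown under LPS, against 34.1 from independent lists, and 258 were lower in both, against 19.3. Both comparisons took the spread of each gene model from the same fit and used the same hairpin and control vector. The numbers from independent lists are thus no exact measure of chance. Without shIrf3 replicates 1, 2 and 3 in turn 202, 225 and 237 were higher in both, without shIrf3_LPS replicates 1 and 3 there were 219 and 245, without shLuc replicates 1, 2 and 3 there were 742, 630 and 249, and without shLuc_LPS replicates 2 and 3 there were 242 and 223. Those lower in both numbered 136 and 154 without shIrf3 replicates 1 and 2, 124 and 132 without shIrf3_LPS replicates 1 and 3, 475 without shLuc replicate 1, and 135 and 124 without shLuc_LPS replicates 2 and 3. The log2 fold changes correlated across the 14970 gene models with Pearson's r = 0.522 and Spearman's rho = 0.473, and gene models are not independent replicates.

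LPS in the luciferase control cells was compared with no LPS. With LPS 639 of 14970 gene models were higher and 666 lower. At least 2-fold changes were found for 157 higher and 90 lower gene models. The gene model uc009gyx.1 on chromosome 7 (53967368 to 53971046, 5 exons) rose from 0.641 ± 0.0865 to 469.5 ± 42.5 CPM (SD, n = 3), a log2 fold change of 9.51 ± 0.14 (SE, edgeR adjusted p = 4.36e-17). The 27-exon gene model uc007kkc.1 on chromosome 11 (78734361 to 78773626) had 1 count over the 3 shLuc libraries and 3161 over the 3 shLuc libraries with LPS, a ratio of 2960 with a 95% counting interval from 531 to 117000. The gene model uc007bqs.1 on chromosome 1 (79431244 to 79436665, 2 exons) fell from 8.82 ± 6.02 to 0.965 ± 0.164 CPM (edgeR adjusted p = 0.0151), and the gene model uc009eml.1 on chromosome 6 (136820956 to 136824326, 4 exons) fell from 10.8 ± 6.27 to 2.41 ± 0.397 CPM (edgeR adjusted p = 0.00379). Of the calls, 49.0% were higher, and 71.9% were with library totals as the only scaling. The call of uc007bqs.1 ended in limma-voom (log2 fold change -2.73, limma-voom adjusted p = 0.148) and without any one shLuc library with LPS, where its log2 fold change lay between -3.30 and -3.06. The log2 fold change of uc009eml.1 was -2.16, and -1.56 without shLuc replicate 1. Fitted from the 6 libraries compared alone, 366 gene models were higher and 302 lower. The shLuc libraries, which differed most among themselves, enter this comparison, so its p-values from the shared fit can be too small. With all 18 libraries in one fit 350 were higher and 345 lower. Without shLuc replicate 2 there were 982 gene models higher and 1150 lower, and without shLuc_LPS replicate 3 there were 365 lower.

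With LPS in the knockdown cells, 624 of 14970 gene models were higher and 575 lower, with at least 2-fold changes for 188 and 53. The gene model uc009gyx.1 rose from 0.908 ± 0.156 to 413.4 ± 39.7 CPM (SD, n = 3), a log2 fold change of 8.84 ± 0.14 (SE, edgeR adjusted p = 7.59e-17). The gene model uc007kkc.1 rose from 0.0592 ± 0.0567 to 31.9 ± 0.248 CPM, with 5 counts over the 3 shIrf3 libraries (edgeR adjusted p = 1.04e-13). The gene model uc007bqs.1 fell from 6.35 ± 0.510 to 1.08 ± 0.373 CPM (edgeR adjusted p = 0.0469), and the gene model uc008rbk.1 on chromosome 3 (113733458 to 113926602, 71 exons) fell from 50.4 ± 5.46 to 15.4 ± 3.84 CPM (edgeR adjusted p = 0.0287). The exons of uc008rbk.1 lie on both strands, so its count can hold reads of overlapping genes. Of the calls, 52.0% were higher, and 65.4% were with library totals as the only scaling. The calls of uc007bqs.1 and uc008rbk.1 ended with library totals only, without any one shIrf3 library and without any one shIrf3 library with LPS. That of uc007bqs.1 also ended without any one shLuc library with LPS, in limma-voom and with no low-count filter. In these cases the log2 fold changes lay from -2.88 to -2.39 for uc007bqs.1 and from -1.86 to -1.53 for uc008rbk.1. Without shIrf3 replicate 1 there were 383 gene models higher and 323 lower, without shIrf3 replicate 3 there were 399 and 356, without shLuc replicate 2 there were 1090 and 1141, without shLuc replicate 1 there were 983 lower, and without shIrf3_LPS replicate 2 there were 324 lower. Fitted from the 6 libraries compared alone, 1323 were higher and 1567 lower. With all 18 libraries in one fit 284 were higher and 337 lower, or 45.7% higher.

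**Figure D2:**
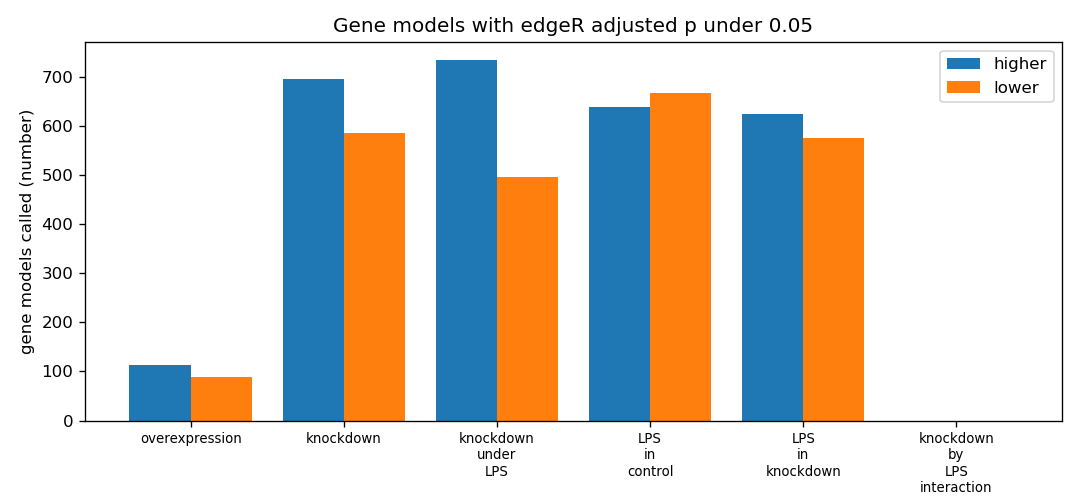
Number of gene models called higher and lower per comparison by edgeR's quasi-likelihood test at an adjusted p under 0.05 (vertical axis, from 0). Bars are counts and carry no error bar. Those of overexpression come from a fit of 6 libraries and the others from a fit of 12 libraries with another detection limit. Bars of different fits are not to be set against each other. Overexpression has 113 higher and 89 lower, and the knockdown by LPS interaction has 0 of each.

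The LPS responses of control and knockdown cells, which share no library, were alike in direction. Of the gene models called in both, 748 of 748 changed in the same direction. A further 557 were called in control cells only and 451 in knockdown cells only, which is no test of a difference between them. There were 400 gene models higher in both, against 26.6 from independent lists, and 348 lower in both, against 25.6, or 569 without shLuc replicate 2. Here too the spread of each gene model came from the same fit, so the lists are not independent. Among the 748, the median size of the log2 fold change was 0.63 in control and 0.57 in knockdown cells. Across gene models the log2 fold changes correlated with Pearson's r = 0.709 and Spearman's rho = 0.507.

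The 7 chromosome M gene models tested had log2 fold changes from -1.61 to 0.49 for knockdown, from 0.25 to 0.83 for knockdown under LPS, from -2.37 to -0.25 for LPS in control and from -0.43 to 0.07 for LPS in knockdown. Without shLuc replicate 1 these ran from 0.50 to 1.29 for knockdown and from -0.26 to 0.54 for LPS in control, and without shLuc replicate 2 from -2.18 to 0.43 and from -2.95 to -0.35. In limma-voom, with every library kept, they ran from 0.22 to 0.55 for knockdown and from -0.49 to -0.23 for LPS in control. Of the 7, edgeR called 1 higher for knockdown, 2 higher for knockdown under LPS and 1 lower for each LPS comparison. Fitted from the 6 libraries compared alone, the numbers were 0 for knockdown, 7 higher for knockdown under LPS, 0 for LPS in control and 5 lower for LPS in knockdown, and with all 18 libraries in one fit they were 0 for each. With library totals only, 4 were higher for knockdown, 4 higher for knockdown under LPS, 0 called for LPS in control and 1 lower for LPS in knockdown. DESeq2 called 3 higher for each knockdown comparison, and for knockdown 2 were higher in limma-voom and 2 of 8 tested with no low-count filter. The call for knockdown ended without shIrf3 replicate 2, shIrf3 replicate 3 or shLuc replicate 3, and 5 were higher without shLuc replicate 1. Those for knockdown under LPS ended without any one library of the 2 groups compared, and 5 and 4 were higher without shLuc replicates 1 and 2. The call for LPS in control ended without shLuc replicate 1, shIrf3 replicate 3, shIrf3_LPS replicate 3 or any one shLuc library with LPS, and 4 were lower without shLuc replicate 2. That for LPS in knockdown ended without any one library of the 2 groups compared, and 3 were lower without shLuc replicate 1.

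Whether knockdown altered the LPS response was tested by the interaction of both factors. In edgeR's quasi-likelihood test 0 gene models were higher and 0 lower, the smallest adjusted p was 0.0513, and 848 had an unadjusted p under 0.05 where 748 are expected by chance. DESeq2 called 10 gene models higher and 5 lower, and limma-voom 0 and 0. Without shLuc replicate 1 edgeR called 4 and 11, without shLuc replicate 2 it called 14 and 2, and without shIrf3 replicate 2 it called 1 higher. An edgeR unadjusted p under 0.05 was found for 1561 gene models without shLuc replicate 1 and 1987 without shLuc replicate 2. Without any one other library that number ran from 658 to 953. For 2 gene models chosen after their values were seen, the interaction was not past the threshold in any alternative run. It was -0.66 ± 0.25 (SE) on the log2 scale for uc009gyx.1 (edgeR adjusted p = 0.782), and -0.34 ± 0.29 for uc007kmt.2 (edgeR adjusted p = 0.960).

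The overexpression arm shares no library with the other arm, so its changes were compared with each of them over 13892 gene models. Its log2 fold changes correlated with those of knockdown at Pearson's r = 0.23 and Spearman's rho = 0.24. With knockdown under LPS the values were 0.31 and 0.27, with LPS in control 0.005 and -0.090, and with LPS in knockdown 0.062 and -0.080. Of the 89 gene models lower with overexpression, 49 were also lower with knockdown, against 3.68 from independent lists (Fisher's exact test, two-sided, Benjamini-Hochberg over 24 tests, adjusted p = 7.20e-44), and 44 were lower with knockdown under LPS, against 3.13 (Fisher's exact test, adjusted p = 7.32e-40). Without Irf3_2D replicates 1, 2 and 3 in turn these shared numbers were 7, 157 and 11 for knockdown and 6, 147 and 10 for knockdown under LPS, and without EGFP replicates 2 and 3 they were 4 and 3 for each. The second was also 27 without shIrf3_LPS replicate 1, shIrf3_LPS replicate 3 or shLuc_LPS replicate 3 and 28 without shLuc_LPS replicate 2. One of the gene models lower in both, chosen after its values were seen, was uc009kic.1, with a log2 fold change of -2.20 ± 0.16 (SE) for overexpression and -2.46 ± 0.19 for knockdown. Of 106 higher with overexpression, 4 were higher with knockdown, against 5.20 (Fisher's exact test, adjusted p = 0.820), and 11 were higher with knockdown under LPS, against 5.47 (Fisher's exact test, adjusted p = 0.0389). For knockdown the number was 1, 37 and 1 without Irf3_2D replicates 1, 2 and 3 in turn, 7, 0 and 0 without EGFP replicates 1, 2 and 3, 2 without shIrf3 replicate 2, and 9 and 8 without shLuc replicates 1 and 2. For knockdown under LPS it was 1, 56 and 4 without Irf3_2D replicates 1, 2 and 3 in turn, 18, 0 and 0 without EGFP replicates 1, 2 and 3, 4 without shIrf3_LPS replicate 1, shIrf3_LPS replicate 3 or shLuc_LPS replicate 3, and 5 without shLuc_LPS replicate 2. With LPS in control cells 21 gene models were higher in both, against 4.63 (Fisher's exact test, adjusted p = 8.97e-09), and 16 that were lower with overexpression were higher with LPS, against 3.89 (Fisher's exact test, adjusted p = 2.25e-06). The first was 0 without Irf3_2D replicate 1, EGFP replicate 2 or EGFP replicate 3, 38 without Irf3_2D replicate 2, 10 without Irf3_2D replicate 3, 33 without EGFP replicate 1, 36 without shLuc replicate 2 and 13 without shLuc_LPS replicate 2. The second was 0 without Irf3_2D replicate 1 or EGFP replicate 3, 69 without Irf3_2D replicate 2, and 1 without Irf3_2D replicate 3 or EGFP replicate 2. With LPS in knockdown cells 34 gene models were higher in both, against 4.48 (Fisher's exact test, adjusted p = 9.39e-21), and 21 that were lower with overexpression were higher with LPS, against 3.76 (Fisher's exact test, adjusted p = 1.72e-10). The 34 became 2 without Irf3_2D replicate 1, 17 without Irf3_2D replicate 3, 0 without EGFP replicate 2 or EGFP replicate 3, and 21 without shIrf3 replicate 1 or shIrf3 replicate 3. The 21 became 1, 70 and 2 without Irf3_2D replicates 1, 2 and 3 in turn, 2 and 1 without EGFP replicates 2 and 3, 10 and 13 without shIrf3 replicates 1 and 2, and 12 and 9 without shIrf3_LPS replicates 1 and 2. The other 8 tests in these 4 comparisons had adjusted p from 0.20 to 0.820 in the same exact test. Among these, 7 gene models were higher with overexpression and lower with knockdown, against 4.38. Lower with overexpression and higher with knockdown was 1, against 4.37, the gene model uc009ocg.2. Its values, also seen before it was chosen here, were -0.88 ± 0.13 (SE) for overexpression and 1.49 ± 0.11 for knockdown. The gene model uc008wjg.1, also chosen after its values were seen, was lower with overexpression (-2.34 ± 0.28, SE) and higher with LPS in control cells (2.07 ± 0.16). Fisher's test takes gene models as independent, which they are not.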

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

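The overlaps and chromosome M ranges without single libraries and the fits without shLuc replicates 1 and 2 together were chosen after the data had been seen. Pairs of numbers are gene models higher and lower. No named gene model reversed under any alternative; over the named gene models and alternatives, 463 log2 fold changes stayed on their side of the threshold and 39 were no longer past it. The cause was not tested for any change given here, except that a fold minimum leaves fewer calls by construction. With a 2-fold minimum the counts were 58 and 79 for knockdown, 98 and 53 for knockdown under LPS, 157 and 90 for LPS in control and 188 and 53 for LPS in knockdown. With all 18 libraries in one fit the counts were 464 and 478 for overexpression, 202 and 184 for knockdown, 205 and 173 for knockdown under LPS, 350 and 345 for LPS in control and 284 and 337 for LPS in knockdown. From only the 6 libraries compared the counts were 235 and 201 for knockdown, 1495 and 1353 for knockdown under LPS, 366 and 302 for LPS in control and 1323 and 1567 for LPS in knockdown. With library totals only the counts were 704 and 345 for knockdown, 491 and 306 for knockdown under LPS, 823 and 321 for LPS in control, 592 and 313 for LPS in knockdown and 0 and 1 for knockdown by LPS interaction. With DESeq2 the counts were 236 and 245 for overexpression and 10 and 5 for knockdown by LPS interaction. With no low-count filter the counts were 128 and 139 for overexpression and 2 and 1 for knockdown by LPS interaction. Without chromosome M gene models the counts were 0 and 1 for knockdown by LPS interaction. Without shLuc replicates 1 and 2 together, where the lone shLuc library is assumed to vary like the other groups, the counts were 1446 and 817 for knockdown and 29 and 37 for knockdown by LPS interaction. Leaving out single libraries gave 0 to 473 higher and 5 to 548 lower for overexpression, 284 to 1623 higher and 226 to 1121 lower for knockdown, 327 to 1329 higher and 198 to 910 lower for knockdown under LPS, 440 to 982 higher and 365 to 1150 lower for LPS in control, 383 to 1090 higher and 323 to 1141 lower for LPS in knockdown and 0 to 14 higher and 0 to 11 lower for knockdown by LPS interaction. Numbers shared between comparisons at a 2-fold minimum, and in parentheses their range without single libraries and without that minimum, were 0 (0 to 37) for overexpression and knockdown higher in both, 18 (3 to 157) for overexpression and knockdown lower in both, 1 (0 to 56) for overexpression and knockdown under LPS higher in both, 16 (3 to 147) for overexpression and knockdown under LPS lower in both, 7 (0 to 38) for overexpression and LPS in control higher in both, 2 (1 to 45) for overexpression and LPS in control lower in both, 7 (0 to 69) for overexpression and LPS in control lower in the first and higher in the second, 16 (0 to 51) for overexpression and LPS in knockdown higher in both, 2 (0 to 31) for overexpression and LPS in knockdown lower in both, 7 (1 to 70) for overexpression and LPS in knockdown lower in the first and higher in the second, 30 (202 to 742) for knockdown and knockdown under LPS higher in both, 37 (124 to 475) for knockdown and knockdown under LPS lower in both, 115 (294 to 550) for LPS in control and LPS in knockdown higher in both and 33 (233 to 569) for LPS in control and LPS in knockdown lower in both.

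Libraries with the same replicate number showed no strong common deviation. In the overexpression arm the correlations of deviations ran from -0.258 to 0.297 over the 3 same-number pairs (median -0.0668). Over its 6 pairs of different numbers they ran from -0.311 to 0.369 (median 0.0541). In the other arm they ran from -0.0251 to 0.106 over the 18 same-number pairs (median 0.0188). Over its 36 pairs of different numbers they ran from -0.101 to 0.0744 (median -0.0226). The same-number pairs lay slightly higher in that arm, so a weak pairing there stays open. With the replicate number as a block the counts were 140 and 96 for overexpression, 761 and 631 for knockdown, 756 and 555 for knockdown under LPS, 660 and 687 for LPS in control, 653 and 644 for LPS in knockdown and 0 and 0 for knockdown by LPS interaction. The call of uc008rbk.1 for LPS in knockdown was not made with the block (log2 fold change -1.70, edgeR adjusted p = 0.0587, against 0.0287), and no other named call changed with it. RLE factors, limma-voom and the filter of 1 CPM in 3 libraries moved no comparison's count of all gene models higher or lower by over 1.5 times. Among chromosome M gene models, limma-voom called 2 higher for knockdown, against 1 in edgeR. Tests of the gene lists and the preset panel are not given, since the gene models could not be named by identifier, and ribosomal RNA genes were left out only as far as they lie on chromosome M. With the depths and spread of that arm, the simulated overexpression test recovered 6 of 67 gene models changed 1.5-fold (8.96%), over 13931 tested. Most changes of that size were thus not detected in the simulated counts, which held no outlying library.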

Other observations

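The tests by chromosome and by number of exons, the comparison over 50 gene models and the split test of the interaction were chosen or fixed in outcome after the data had been seen. Over 5 comparisons and 22 groups each, a larger share of the gene models tested on chromosome 1 was called for overexpression than of those elsewhere, with 21 higher and 6 lower of 826 tested (3.27% against 1.34%, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.00291), and a smaller share on chromosome 4, with 3 higher and 0 lower of 864 (0.347% against 1.52%, Fisher's exact test, adjusted p = 0.0411). Chromosome 19 had as high a share as chromosome 1 over fewer gene models, with 7 higher and 9 lower of 489 (3.27% against 1.38%, Fisher's exact test, adjusted p = 0.0506), which did not pass. Chromosomes 1 and 4 did not pass in the other 4 comparisons, where the adjusted p of chromosome 1 lay between 0.509 and 0.913. Gene models with 1 exon were called less often than others with knockdown (4.78% against 8.75%, Fisher's exact test, adjusted p = 0.00291), with knockdown under LPS (4.23% against 8.41%, adjusted p = 0.00188 in the same exact test) and with LPS in control cells (5.46% against 8.89%, adjusted p = 0.0264 in the same exact test). The difference did not pass for overexpression (0.464% against 1.498%, adjusted p = 0.213 in the same exact test) or for LPS in knockdown (6.00% against 8.11%, adjusted p = 0.294 in the same exact test). The tests by chromosome and exon number used the main fits only, and the overexpression calls moved with single libraries. They were not matched on abundance or exon length, so a difference in detection cannot be told apart from other sources. These tests take gene models as independent, which they are not.

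Gene models lower with overexpression were also lower with knockdown, 49 of 89, although the labels name opposite changes of IRF3. In 10000 random draws matched on mean CPM and exon length, the highest number shared was 14, which argues against abundance and length as the cause. Without each library in turn, the number shared stayed at least 7.03 times that of independent lists, which argues against any 1 library as the cause, although the number itself ran from 3 to 157. No biological explanation was tested, the labels do not say what 2D stands for, and a difference between control and IRF3 vectors that both arms have in common stays open.

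Irf3_2D replicate 2 stood apart from the other libraries of its arm and accounted for 54.6% of the squared deviations in its group. After all 6 libraries had been thinned to equal totals the share was 53.5%, which argues against its lower depth. Its deviation correlated with exon length across gene models at a Spearman rho of -0.155, between the bounds set in advance, while EGFP replicate 3 reached -0.210, so a length trend cannot be told apart from other sources. Of the gene models called without it, 1017 were also tested with all 6 libraries. Over these, replicate 2 showed a median share of 0.372 of the change seen in the other Irf3_2D libraries. The share was 0.944 for replicate 1 over 13 and 0.861 for replicate 3 over 55. This met the criterion set in advance for a smaller response. These sets differ in size and in how far their changes were selected, so after this had been seen the shares were also taken over the 50 gene models of smallest p in each case, where they were 0.765 for replicate 2, 0.993 for replicate 1 and 0.859 for replicate 3, and a smaller response to the vector stays open.

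The other splits of the libraries were too few for a share under 0.05 in the comparisons of 3 with 3 libraries, where 10 splits exist. Fitted from its 6 libraries, overexpression gave 202 calls, knockdown 436, knockdown under LPS 2848, LPS in control 668 and LPS in knockdown 2890, each in 1 of 10 splits, and the highest other split gave 0 in each. For the interaction the real count was 0, which all 100 of 100 splits drawn from the 12 libraries reach by construction, with a highest of 2, so the splits say nothing about chance there.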
